A study of Saccharomyces cerevisiae with 36 samples.

How the data were processed

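RNA sequencing of budding yeast was analysed in 36 libraries. They came from 2 strains of the W303 Ade+ background, one with an mCherry tag on the RNA helicase Ded1 (WT) and one with the same tag on the allele labelled Ded1_IDRm (IDRm). Cells were held for 10 min at 30, 40 or 42 °C, and RNA was taken as total RNA, from the pellet and from the soluble part. Each of the 18 groups of strain, temperature and fraction held 2 libraries. Per the labels' protocols, each strain was inoculated in duplicate, each main culture was split over the 3 temperatures, cells were filtered and flash frozen, RNA was extracted with hot acid phenol, and ribosomal RNA was depleted. The replicates therefore came from separate cultures, while libraries of 1 culture at different temperatures and fractions share their source. That a replicate number stands for 1 culture throughout was taken from these protocols and is not stated in words.

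Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.19.1 and aligned with STAR 2.5.2b to the R64 genome. The deposited values are raw read counts per gene, whole numbers without normalisation. The tool that counted the reads, the strandedness and the annotation release are not given in the sources used here. Values of paralogs with near-identical sequence and of overlapping or antisense genes are therefore uncertain. The table held 6697 genes, of which 6014 were matched by locus tag to the R64 annotation, 6008 of them protein-coding. The 683 genes without a match held 0.277% of the counts and stayed in the tests, but none of them is named. In all 36 libraries 226 genes had a count of 0, 98 of them matched. Ribosomal RNA genes and small nucleolar RNA genes were not among the genes of the table. Library totals ran from 4934241 to 13730247 counts, and were lowest for soluble RNA.

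Genes were tested with the edgeR quasi-likelihood test with robust dispersion (edgeR 4.0.16, limma 3.58.1, R 4.3.3), TMM scaling and filterByExpr at a minimum count of 10. The 12 total libraries were fitted together with 1 term per group (6090 genes, 6 residual degrees of freedom, 9 contrasts). The 24 pellet and soluble libraries were fitted in a separate model (6141 genes, 12 residual degrees of freedom, 11 contrasts). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Fold changes are log2 values with the standard error of the fit, and rest on 2 libraries per group. Levels of single genes are CPM of library totals multiplied by their TMM factors, except in the figure of marker levels, which has no TMM factors. All libraries were scaled within themselves, so a fold change is relative to the other transcripts of the same RNA and not to the cell. The pellet-soluble difference of a gene is the log2 ratio of pellet to soluble level, and its shift is the change of that ratio between temperatures. The difference between strains in a temperature effect was tested as an interaction term.

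Before the data were examined, the groups, the contrasts, 18 gene lists, most alternatives and the rule for naming genes were fixed. The lists were Hsf1 heat shock chaperones, Msn2/4 general stress genes, ribosomal proteins, ribosome biogenesis factors, translation initiation factors, translation elongation and termination factors, glycolysis and fermentation, proteasome subunits, the nuclear-encoded respiratory chain, mitochondrially encoded mRNAs, mitochondrial ribosomal proteins, ER translocation and glycosylation, plasma membrane transporters, cell wall proteins, amino acid biosynthesis, histones, glucose-repressed genes, and small nucleolar and spliceosomal RNAs. The last had 0 measured members, which left 17. Lists were tested with camera at a preset correlation of 0.01 and a prior count of 1, with camera at an estimated correlation, and with fry, each adjusted over the lists of a contrast by the Benjamini-Hochberg method. Members were also called with p-values adjusted over the list alone. Of the 20 contrasts together, camera at the preset correlation called 169 list results, and 15 of them held with an estimated correlation. Named genes were, for each contrast, the 5 highest and 5 lowest called protein-coding genes with a standard name and an average of at least 32 CPM, up to 3 called members of each list with the largest absolute change, and DED1, HSP104, SSA4, HSP42, HSP26, HSP12, PAB1, PMA1 and RPL3 always. A gene outside that rule is named as chosen after its values were seen.

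The insoluble share of mRNA was estimated for each of the 12 harvests. The total level of each gene in CPM was modelled as a weighted sum of its soluble and pellet levels, with 1 pair of weights for all genes, by least squares of the log ratio over genes with at least 50 counts in all 3 libraries. The share is the pellet weight over the sum of both weights. It assumes that each fraction library represents its fraction without loss of particular transcripts.

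The model steps were tested on simulated counts with known changes at the real depths. For the total 42 against 30 °C comparison of WT, 62.7% of 1.5-fold, 94.0% of 2-fold and all of the 4-fold changes were recovered (6049 genes). For the strain difference of that effect the recovery was 20.9%, 76.1% and 100% (6044 genes). For the pellet-soluble shift of WT at 42 °C it was 5.97%, 55.2% and 95.5% (6092 genes), and for its strain difference 4.48%, 20.9% and 77.3% (6091 genes). Simulated insoluble shares of 5, 20 and 35% with gene noise of 0.4 log2 were recovered between 4.52 and 5.52%, 19.2 and 20.9%, and 34.3 and 35.7%. The simulated totals were built from the same soluble and pellet levels that were fitted, with noise in the total alone. Errors in the fraction libraries were therefore not simulated. In the real fits the root mean square misfit ran from 0.217 to 0.564 log2, the highest in the first WT harvest at 30 °C.

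Whether libraries of the same number go together was checked on the replicate differences. Within a harvest, 11 of 18 pairs of fractions had a correlation across genes above 0.1 (from -0.22 to 0.72). Total libraries of 1 culture number at different temperatures gave 0 of 6 (from -0.30 to 0.04). With the pellet and soluble libraries included, 8 of 30 pairs of 1 culture number at different temperatures were above 0.1 (from -0.55 to 0.31), all of them pairs of fraction libraries. The main models held no replicate term, and models with a term for the culture or the harvest were run as alternatives. Further alternatives were RLE scaling, no filter, a minimum count of 50, nuclear protein-coding genes alone, DESeq2 1.42.0 on the same genes and design, a model of only the groups compared, pellet against total in place of soluble, a share minimum of 200 counts, least absolute deviations for the share, and leaving out each library in turn. Removal of a trend with coding GC content, alone and with the culture term, removal of a trend with coding length from the share, leaving out the second WT harvest at 30 or at 42 °C, and replicate terms with exchanged numbers were chosen after the data were seen. Coordinates are those of R64 genes. No library was left out of the main models. Figures were drawn from the result tables with matplotlib in Python.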

Results

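Transcript levels were measured in total, insoluble (pellet) and soluble RNA of yeast cells held for 10 min at 30, 40 or 42 °C. The strains carried tagged Ded1, an RNA helicase that helps ribosomes scan mRNAs (WT), or the tagged Ded1_IDRm allele (IDRm). Each of the 18 groups held 2 libraries, and libraries held between 4934241 and 13730247 counts. Correlations between replicates ranged from 0.984 to 0.995 for total RNA, from 0.980 to 0.998 for pellets and from 0.957 to 0.993 for soluble RNA. Levels in CPM are TMM-scaled in the text. Values after ± are standard errors of log2 fold changes unless named as SD. "Called" means an adjusted p under 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg).

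The gene that differs between the strains is DED1 (YOR204W, chromosome XV, 722911 to 724725, R64). In total RNA at 30 °C its level was 1721 CPM (SD 385, n = 2) in WT and 1080 CPM (SD 134, n = 2) in IDRm, a log2 difference of -0.67 ± 0.17. The difference was called. It was not called without WT 30 °C total replicate 1 (-0.46), not without IDRm 30 °C total replicate 1 (-0.57), and not in a model of those 2 groups alone (-0.68). DED1 was not called in total RNA at 40 or 42 °C against 30 °C in WT (-0.20 ± 0.17 and -0.35 ± 0.17) or IDRm (-0.21 ± 0.17 and -0.11 ± 0.17). In WT it was called without WT 30 °C total replicate 2 (-0.44 and -0.60) and at 42 °C without WT 42 °C total replicate 2 (-0.63). In the pellets at 30 °C the levels were 1425 CPM (SD 8.20) in WT and 1556 CPM (SD 116) in IDRm. In soluble RNA they were 1169 CPM (SD 81.6) and 1260.0 CPM (SD 53.9). Reads from a recoded part of the allele would not align to R64, and the sequence of the allele was not used here.

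The first comparison asks how 10 min of heat changed the transcripts of WT cells. At 40 °C HSP26 (YBR072W), a small heat shock protein, was among the genes that rose most in WT, by 7.17 ± 0.22 on the log2 scale, and HSP12 (YFL014W), a membrane-stabilising stress protein, rose by 7.42 ± 0.39. HSP30, a plasma membrane heat shock protein, rose by 6.98 ± 0.43, and SPG4 and TMA10 by 7.89 ± 0.35 and 6.97 ± 0.25. Without WT 30 °C total replicate 1 SPG4 was 8.52 and HSP12 8.15, and without replicate 2 HSP30 was 7.73. HSP104 (YLL026W, chromosome XII, 88623 to 91349), which dissolves protein aggregates, rose from 673 CPM (SD 93.6) to 22168 CPM (SD 14.5). SSA4 (YER103W, chromosome V, 364589 to 366517), a heat-inducible Hsp70, rose from 337 CPM (SD 122) to 29460.3 CPM (SD 2022). The lowest values were those of NSR1 (YGR159C), a nucleolar protein, -5.75 ± 0.37, CIC1 -4.58 ± 0.35, REI1 -4.46 ± 0.24, ALB1 -4.42 ± 0.28 and the phosphate transporter PHO84 -4.52 ± 0.28. In all, 4244 of 6090 genes were called, 2260 higher and 1984 lower, and 2131 of them by at least 2-fold.

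All 27 Hsf1 chaperone genes rose at 40 °C in WT (median 3.92, camera adjusted p = 2.83e-14, and adjusted p = 0.00391 with an estimated correlation). Of 28 Msn2/4 stress genes, 27 rose, among them DDR2 (6.58 ± 0.35), with a median of 3.53 (camera adjusted p = 4.33e-13, but adjusted p = 0.303 with an estimated correlation). Of 52 ribosome biogenesis genes, 50 fell (median -2.49, camera adjusted p = 2.08e-17, adjusted p = 0.34 with an estimated correlation), PWP1 by 4.17 ± 0.19 among them. Of 134 ribosomal protein genes, 127 fell, 128 adjusted over the list alone (median -1.09, camera adjusted p = 1.2e-18, adjusted p = 0.34 with an estimated correlation), with RPS9A at -2.69 ± 0.13 and RPL3 at -1.36 ± 0.13. Of 26 translation initiation factor genes, 21 fell, with TIF5 at -2.35 ± 0.15, NIP1 at -2.30 ± 0.13 and PAB1, the poly(A)-binding protein, at -1.42 ± 0.28 (camera adjusted p = 6.86e-06, adjusted p = 0.303 with an estimated correlation). Of 10 elongation and termination factor genes 7 fell, SUP45 by 2.02 ± 0.16 (camera adjusted p = 0.0159, adjusted p = 0.34 with an estimated correlation). Of 48 amino acid biosynthesis genes, 37 fell and 2 rose, or 37 and 3 adjusted over the list alone, with ILV5 at -3.38 ± 0.15 and MET6 at -2.90 ± 0.15 (camera adjusted p = 3.08e-08, adjusted p = 0.303 with an estimated correlation).

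Genes of respiration and of growth without glucose moved up in WT at 40 °C. Of 34 nuclear respiratory chain genes, 23 rose and 1 fell, with QCR8 at 2.29 ± 0.17 (camera adjusted p = 0.00481, adjusted p = 0.477 with an estimated correlation). Of 20 glucose-repressed genes, 13 rose and 1 fell, with the carnitine carrier CRC1 at 2.55 ± 0.22 (camera adjusted p = 0.00659, adjusted p = 0.477 with an estimated correlation). The other lists were not called by camera at 40 °C. Of 8 mitochondrially encoded mRNAs 6 rose (median 0.62, or 0.18 with the GC trend removed, camera adjusted p = 0.0969). Of 33 genes of the proteasome list, 14 rose and 3 fell, or 12 and 2 adjusted over the list alone (camera adjusted p = 0.207). Its largest change was in RPN4 (3.13 ± 0.12), which is a transcription factor for proteasome genes and not a subunit. ER translocation and glycosylation had 12 of 29 higher and 6 lower, with the disulfide-forming oxidase ERO1 at 3.77 ± 0.14 (camera adjusted p = 0.449). Mitochondrial ribosomal proteins had 11 of 66 higher and 24 lower (camera adjusted p = 0.109). Plasma membrane transporters had 14 of 37 higher and 19 lower (camera adjusted p = 0.205), with HXT5 at 6.45 ± 0.15. Glycolysis had 5 of 16 higher and 1 lower (camera adjusted p = 0.461), with TDH1 at 2.51 ± 0.14. Histones had 4 of 10 higher and 1 lower (camera adjusted p = 0.461). Cell wall proteins had 7 of 27 higher and 5 lower (camera adjusted p = 0.966).

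At 42 °C against 30 °C, the highest values in WT included BTN2, which sorts misfolded protein, at 7.05 ± 0.40, HSP30 at 6.42 ± 0.42, SPG4 at 6.37 ± 0.40, HSP42 at 6.18 ± 0.32 and HSP26 at 5.97 ± 0.21. Without WT 30 °C total replicate 1 SPG4 was 6.99, and without replicate 2 BTN2 was 7.90, HSP30 7.15 and HSP42 6.95. The lowest were ADE17, of purine synthesis, -3.93 ± 0.15, the carbonic anhydrase NCE103 -3.10 ± 0.15, GCV2 -2.93 ± 0.15, pyruvate carboxylase PYC1 -2.83 ± 0.14 and the phosphate transporter PHO89 -2.73 ± 0.18. In all 3738 genes were called, 2026 higher and 1712 lower. All 27 Hsf1 genes rose (median 2.87, camera adjusted p = 1.21e-15, and adjusted p = 0.00274 with an estimated correlation). Of 28 Msn2/4 genes 25 rose, 26 adjusted over the list alone (median 1.94, camera adjusted p = 7.11e-10, adjusted p = 0.405 with an estimated correlation). Of 134 ribosomal protein genes 59 fell and 2 rose, or 53 and 2 adjusted over the list alone (median -0.34, camera adjusted p = 8.29e-06, adjusted p = 0.723 with an estimated correlation). Of 52 ribosome biogenesis genes 28 fell and 2 rose (median -0.49, camera adjusted p = 0.000588, adjusted p = 0.723 with an estimated correlation). Of 48 amino acid biosynthesis genes 34 fell and 1 rose (camera adjusted p = 6.74e-09, adjusted p = 0.381 with an estimated correlation).

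Set directly against 40 °C, 2859 genes were called at 42 °C in WT, 1499 higher and 1360 lower. NSR1 was higher at 42 than at 40 °C by 4.44 ± 0.36, and CIC1 by 4.18 ± 0.35. YAP6 was higher by 3.69 ± 0.22 and PWP1, of ribosome assembly, by 3.57 ± 0.18. HSP12 was lower (-3.54 ± 0.32), as were the glucose transporter HXT7 (-3.23 ± 0.34), the catalase CTT1 (-3.05 ± 0.15), ALD3 (-3.05 ± 0.21) and UIP4 (-3.04 ± 0.19). All 52 ribosome biogenesis genes were higher (median 1.99, camera adjusted p = 7.09e-25, adjusted p = 0.286 with an estimated correlation). The same held for 126 of 134 ribosomal protein genes, or 130 with 1 lower adjusted over the list alone (median 0.82, camera adjusted p = 8.02e-21, adjusted p = 0.349 with an estimated correlation). Of 27 Hsf1 genes 20 were lower, or 20 with 1 higher adjusted over the list alone (median -0.63, camera adjusted p = 6.29e-07, adjusted p = 0.0326 with an estimated correlation). Of 28 Msn2/4 genes 25 were lower, or 26 adjusted over the list alone (median -1.53, camera adjusted p = 1.31e-14, adjusted p = 0.286 with an estimated correlation).

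The same heat was given to IDRm cells. At 40 °C HSP30 (YCR021C) rose by 10.17 ± 0.51, HSP26 by 8.94 ± 0.24, HSP12 by 8.87 ± 0.42, SPG4 by 8.28 ± 0.27 and TMA10 by 8.06 ± 0.27. NSR1 (-5.20 ± 0.34), REI1 (-4.82 ± 0.23), ALB1 (-4.62 ± 0.26), CIC1 (-4.53 ± 0.32) and the ribosome assembly GTPase NOG2 (-4.51 ± 0.19) fell most. HSP30 was 10.94 without IDRm 30 °C total replicate 1. Without IDRm 40 °C total replicate 2 NSR1 was -5.96, REI1 -5.51, ALB1 -5.45 and CIC1 -5.13. In all 4288 genes were called, 2303 higher and 1985 lower. All 27 Hsf1 genes rose (median 4.26, camera adjusted p = 1.91e-14, and adjusted p = 0.00377 with an estimated correlation). Of 28 Msn2/4 genes 27 rose and 1 fell (median 4.13, camera adjusted p = 2.71e-13, adjusted p = 0.311 with an estimated correlation). All 52 ribosome biogenesis genes fell (median -3.12, camera adjusted p = 6.48e-20, adjusted p = 0.374 with an estimated correlation). For ribosomal proteins, 122 of 134 genes fell and 1 rose (camera adjusted p = 1.06e-16, adjusted p = 0.374 with an estimated correlation). Of 34 respiratory chain genes 27 rose, or 27 with 1 lower adjusted over the list alone (median 1.04, camera adjusted p = 4.22e-05, adjusted p = 0.38 with an estimated correlation).

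At 42 °C against 30 °C in IDRm, HSP30 rose by 9.88 ± 0.51, HSP26 by 8.28 ± 0.23, BTN2 by 7.62 ± 0.43, HSP42 by 7.40 ± 0.35 and HSP12 by 7.33 ± 0.40. HSP30 was 10.67 without IDRm 30 °C total replicate 1. ALB1 (-3.68 ± 0.25), NCE103 (-3.23 ± 0.15), PHO89 (-3.09 ± 0.19) and ADE17 (-2.98 ± 0.15) were among the lowest of 3944 called genes, 2055 higher and 1889 lower. All 27 Hsf1 genes rose (median 3.64, camera adjusted p = 1.09e-15, and adjusted p = 0.0027 with an estimated correlation). For Msn2/4, 27 of 28 genes rose and 1 fell (median 2.90, camera adjusted p = 3.61e-13, adjusted p = 0.382 with an estimated correlation). All 52 ribosome biogenesis genes fell (median -1.42, camera adjusted p = 3.19e-14, adjusted p = 0.595 with an estimated correlation), with SOF1 at -2.66 ± 0.20. Of 134 ribosomal protein genes 69 fell and 1 rose, or 67 and 1 adjusted over the list alone (median -0.40, camera adjusted p = 1.29e-06, adjusted p = 0.801 with an estimated correlation). Against 40 °C, 2573 genes were called, 1289 higher and 1284 lower, or 1617 without IDRm 40 °C total replicate 1. NIS1 (3.25 ± 0.19), NSR1 (3.13 ± 0.33), PUF6 (2.95 ± 0.27), PAC1 (2.80 ± 0.14) and YAP6 (2.58 ± 0.21) were highest, and ALD3 (-2.49 ± 0.20), TKL2 (-2.40 ± 0.14), UIP4 (-2.36 ± 0.17), SPC110 (-2.30 ± 0.35) and GND2 (-2.28 ± 0.24) lowest. NSR1 was 3.90 without IDRm 40 °C total replicate 2. Of 52 ribosome biogenesis genes 49 were higher at 42 than at 40 °C (camera adjusted p = 5.86e-22, adjusted p = 0.249 with an estimated correlation). Of the chaperones, 14 of 27 Hsf1 genes were lower and 1 higher (camera adjusted p = 6.29e-05, adjusted p = 0.0932 with an estimated correlation).

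**Figure D1:**
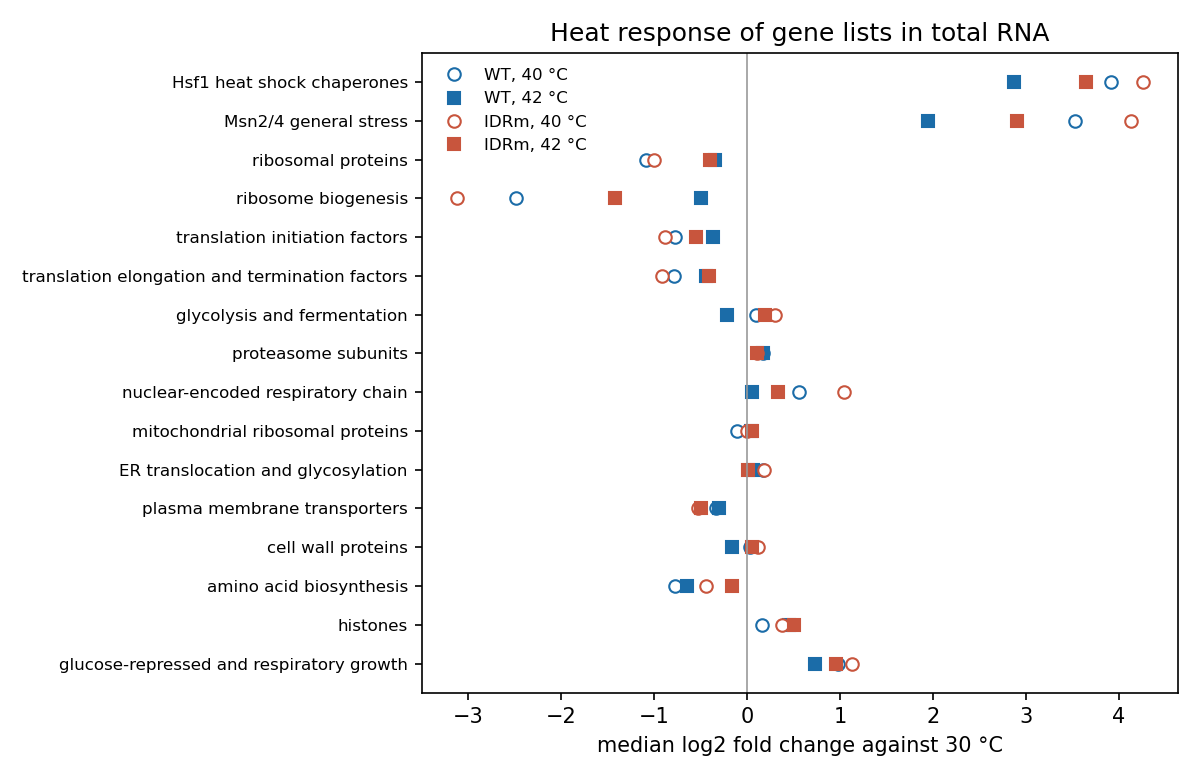
Median log2 fold change of each gene list in total RNA against 30 °C (horizontal axis), for WT (blue) and IDRm (red) at 40 °C (open circles) and 42 °C (filled squares), 2 libraries per group. The Hsf1 median was 3.92 in WT and 4.26 in IDRm at 40 °C, and the ribosome biogenesis median at 42 °C was -0.49 in WT and -1.42 in IDRm. Some medians near 0, among them some of those of cell wall and mitochondrial ribosomal proteins, change sign with RLE scaling.

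**Figure D2:**
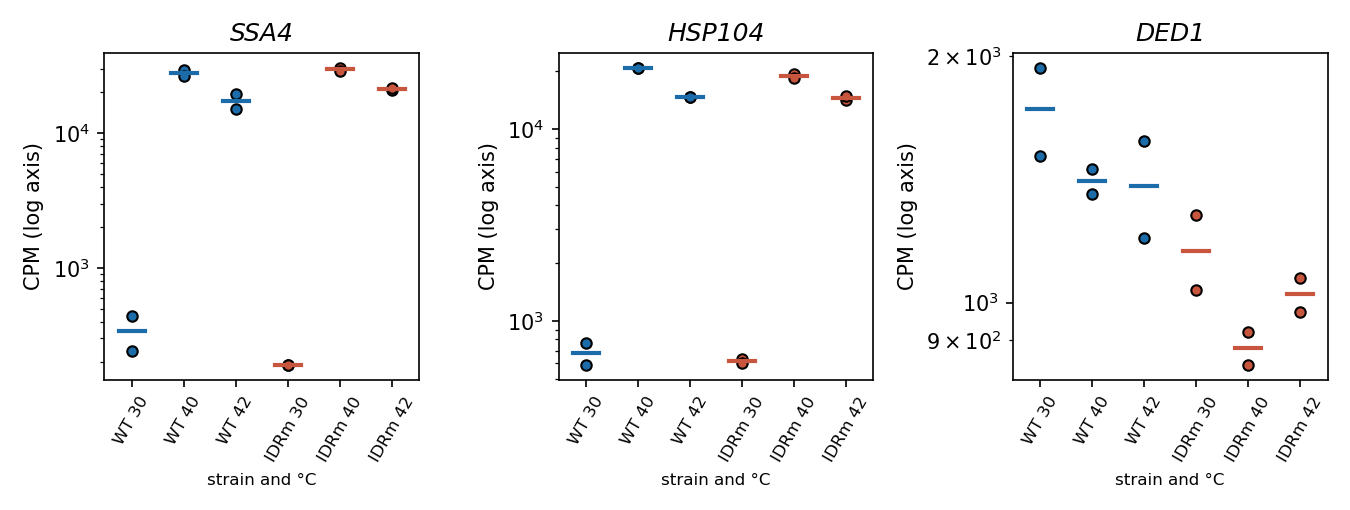
CPM of SSA4, HSP104 and DED1 in total RNA, without TMM factors, on a log axis, by strain and temperature, with 1 point per replicate and lines through the means of 2 replicates. SSA4 and HSP104 were higher at 40 and 42 °C than at 30 °C in both strains, while DED1 was not called between temperatures in either.

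How the strains differed before heat was asked at 30 °C. Among the genes lowest in IDRm was HSP30, by 7.98-fold. On the log2 scale, HSP26 was at -1.58 ± 0.19, the ammonium permease MEP2 at -1.63 ± 0.13 and SOL4 at -1.59 ± 0.27. HSP42 (-1.66 ± 0.34) was also among the lowest, but was not called without IDRm 30 °C total replicate 1 (-1.83) or replicate 2 (-1.53). SSA4 was lower by -0.92 ± 0.20, not called without IDRm 30 °C total replicate 1 (-0.96) or replicate 2 (-0.90), and HSP104 was not called (-0.23 ± 0.13). These 4 heat shock genes were higher in WT 30 °C total replicate 2 than in replicate 1. Without replicate 2 HSP30 was -2.24, HSP26 -1.27, HSP42 -0.87 and SSA4 -0.50, smaller but all called. The amino acid permease GAP1 (-1.35 ± 0.14), and SER3, MET17 and MET3 of amino acid synthesis (-1.33 ± 0.10, -1.28 ± 0.19 and -1.21 ± 0.11), were also lower. The highest were VAR1, a mitochondrially encoded ribosomal protein (2.72 ± 0.44), SLK19 (2.13 ± 0.35) and MAD1 (2.04 ± 0.34) of chromosome segregation, and the ribosome assembly genes NOP53 (1.95 ± 0.27) and PXR1 (1.79 ± 0.19). With the GC trend removed these were 2.17, 1.88, 1.79, 1.74 and 1.83. Without WT 30 °C total replicate 1 VAR1, SLK19, MAD1 and NOP53 were 2.08, 1.60, 1.51 and 1.51, and without replicate 2 they were 3.98, 3.01, 2.89 and 2.55. HSP30 was -3.83 without IDRm 30 °C total replicate 1.

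Of 6090 genes, 787 were called between the strains at 30 °C, 483 higher and 304 lower in IDRm. That count was 80.0 in a model of those 2 groups alone. It also changed widely when 1 of their libraries was left out, and 28 of the 48 called named genes lost the call in at least 1 of these leave-out fits. Of 27 Hsf1 genes 10 were lower, 13 adjusted over the list alone (median -0.26, camera adjusted p = 1.95e-06, and adjusted p = 0.0403 with an estimated correlation). In WT, 16 of these 27 genes were higher in 30 °C total replicate 2 than in replicate 1, with a median ratio over all 27 of 1.03. Over the 21 strongly induced ones the median ratio was 1.22. Of 52 ribosome biogenesis genes 22 were higher, or 31 with 1 lower adjusted over the list alone (median 0.46, camera adjusted p = 2.09e-08, adjusted p = 0.472 with an estimated correlation), with LOC1 at 1.42 ± 0.16 and EBP2 at 1.28 ± 0.21. Of 134 ribosomal protein genes 30 were lower, 44 adjusted over the list alone (median -0.37, camera adjusted p = 1.58e-13, adjusted p = 0.472 with an estimated correlation). Of 16 glycolysis genes 7 were lower, 13 adjusted over the list alone (camera adjusted p = 1.25e-06, adjusted p = 0.472 with an estimated correlation), with PGK1 at -0.85 ± 0.15 and TDH2 at -0.80 ± 0.13. Of 48 amino acid biosynthesis genes 11 were lower and 1 higher, or 20 and 3 adjusted over the list alone (camera adjusted p = 9.66e-06, adjusted p = 0.472 with an estimated correlation).

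Whether IDRm changed the response to heat was tested as the difference between the strains' temperature effects. The genes that rose further at 42 °C in IDRm than in WT included HSP30 by 3.47 ± 0.55, HSP12 by 3.45 ± 0.51, HXT7 by 3.17 ± 0.49, the hexokinase HXK1 by 3.07 ± 0.38, the phosphoglucomutase PGM2 by 2.48 ± 0.23 and HSP26 by 2.30 ± 0.26. HSP12, for instance, stood at 164 CPM (SD 45.4) in WT and 1012 CPM (SD 255) in IDRm at 42 °C. For HSP30 and HSP26 much of the difference lay at 30 °C. HSP30 stood at 50.4 CPM (SD 29.2) in WT and 6.39 CPM (SD 3.95) in IDRm at 30 °C, and at 4331 CPM (SD 435) and 5995 CPM (SD 245) at 42 °C. HSP26 stood at 49.0 CPM (SD 13.9) and 16.5 CPM (SD 2.41) at 30 °C, and at 3090 CPM (SD 114) and 5103 CPM (SD 742) at 42 °C. Without WT 30 °C total replicate 2 the differences were 2.71 for HSP30 and 1.99 for HSP26, both called, and without IDRm 30 °C total replicate 1 HSP30 was 4.29. Without WT 30 °C total replicate 1 HSP12, HXT7 and HXK1 were 2.72, 2.32 and 2.39, and without replicate 2 their fold differences were 16.0, 13.6 and 11.8. The difference was negative for SLK19 (-4.24 ± 0.49), MAD1 (-3.64 ± 0.48), NOP53 (-3.52 ± 0.39), and VAR1 (-3.49 ± 0.59). With the GC trend removed these were -3.70, -3.12, -3.10 and -2.14. They were -3.71, -3.11, -3.08 and -2.85 without WT 30 °C total replicate 1, and -5.12, -4.49, -4.12 and -4.75 without replicate 2. Of the 717 called genes 318 were positive and 399 negative. Of 28 Msn2/4 genes 20 were positive and 1 negative, or 24 and 1 adjusted over the list alone (mean 1.31, camera adjusted p = 2.18e-17, adjusted p = 0.176 with an estimated correlation). Of 27 Hsf1 genes 8 were positive, 11 adjusted over the list alone (median 0.45, camera adjusted p = 2.89e-08, and adjusted p = 0.0197 with an estimated correlation), among them SSA3 (1.26 ± 0.18) and SSA4 (1.22 ± 0.29), the latter 0.80 without WT 30 °C total replicate 2 and not called without WT 42 °C total replicate 1 (1.02) or IDRm 30 °C total replicate 1 (1.26). In the WT baseline at 30 °C, 16 of these 27 genes were higher in total replicate 2 than in replicate 1, with a median ratio over all 27 of 1.03. That ratio was 1.22 over the 21 strongly induced ones.

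Ribosome biogenesis genes fell further at 42 °C in IDRm, with 36 of 52 called negative, 45 adjusted over the list alone (median -0.88, camera adjusted p = 2.48e-20, adjusted p = 0.321 with an estimated correlation), EBP2 (-2.57 ± 0.31) and LOC1 (-2.28 ± 0.23) leading. Part of this lay at 30 °C, where the list was 0.46 higher in IDRm than in WT, and it was 0.50 lower at 42 °C. Amino acid biosynthesis had 12 of 48 genes positive, 22 adjusted over the list alone (median 0.44, camera adjusted p = 9.35e-11, adjusted p = 0.176 with an estimated correlation), with ARG1 at 1.54 ± 0.17 and SER3 at 1.17 ± 0.15. The mitochondrially encoded mRNAs had 2 of 8 negative and a median of -0.44, which was 0.23 with the GC trend removed (camera adjusted p = 0.00148, adjusted p = 0.321 with an estimated correlation). HSP104 (0.23 ± 0.19), PAB1 (-0.61 ± 0.39) and DED1 (0.24 ± 0.24) were not called. The count of 717 was 473 without WT 30 °C total replicate 1, 1509 without WT 30 °C replicate 2 and 395 without WT 42 °C replicate 1. It was 213 without IDRm 30 °C replicate 1, 275 without IDRm 42 °C replicate 1 441 without IDRm 42 °C replicate 2, and 408 in a model of those 4 groups alone.

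At 40 °C the strains' responses differed in fewer genes, 100 in all, 61 positive and 39 negative. HSP26 (1.77 ± 0.26), the glucose transporter HXT6 (3.24 ± 0.49), XBP1 (1.98 ± 0.26), the invertase SUC2 (1.54 ± 0.19) and SSA3 (1.21 ± 0.18) rose further in IDRm and kept the call without any 1 library, as did BRE5 (-1.25 ± 0.19). HXT6 was 2.64 without IDRm 30 °C total replicate 1 and 4.30 without replicate 2. HSP30 (3.18 ± 0.54) was 2.40 without WT 30 °C total replicate 2 and 3.99 without IDRm 30 °C total replicate 1. It was not called without WT 40 °C total replicate 1 (3.20) or 2 (3.21) or IDRm 40 °C replicate 1 (3.24) or 2 (3.17). Of 28 Msn2/4 genes 6 were positive and 1 negative, or 15 and 1 adjusted over the list alone (median 0.60, camera adjusted p = 1.49e-09, adjusted p = 0.418 with an estimated correlation). Of 27 Hsf1 genes 2 were positive, or 4 adjusted over the list alone (camera adjusted p = 6.15e-05, adjusted p = 0.0886 with an estimated correlation). The count was 739 without WT 30 °C total replicate 2, 43 without WT 40 °C replicate 1. It was 36 without IDRm 30 °C replicate 2, 36 without IDRm 40 °C replicate 1, and 16 without WT 40 °C replicate 2, IDRm 30 °C replicate 1 or IDRm 40 °C replicate 2. DESeq2 called 174, and a model of the 4 groups alone 43.

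What separated pellet from soluble RNA without heat was asked in each strain at 30 °C. In WT, the highest included the potassium transporter TRK2 (YKR050W, chromosome XI, 527815 to 530484) at 3.04 ± 0.16, with TVS1 2.78 ± 0.18, CLG1 2.75 ± 0.17, PSR1 2.74 ± 0.17 and AZR1 2.74 ± 0.18. With total in place of soluble RNA TRK2 was higher by 2.82-fold, which is below CLG1 and TVS1. On the log2 scale TVS1 was 1.88 there, CLG1 2.76, PSR1 1.29 and AZR1 1.18, and all of these genes were called. TRK2, TVS1 and AZR1 were among the 61 genes, described below, whose soluble levels differed between the strains. The lowest were CHZ1, a histone chaperone, -3.42 ± 0.45, LOC1 -2.88 ± 0.46, the histone gene HHF2 -2.85 ± 0.16, TMA7 -2.84 ± 0.43 and NOP10 -2.80 ± 0.53. CHZ1 was -1.41 and LOC1 -1.07 with total in place of soluble RNA. In IDRm, FUN19 (2.58 ± 0.19), CLG1 (2.41 ± 0.17), TOS2 (2.23 ± 0.17), FKS3 (2.13 ± 0.14) and REA1 (2.11 ± 0.21) were highest and TMA7 (-3.13 ± 0.42), RPL29 (-3.10 ± 0.72), NOP10 (-3.10 ± 0.52), and ECM15 (-2.98 ± 0.40) lowest. Without IDRm 30 °C soluble replicate 1 RPL29 was -2.27 and NOP10 -2.5. The counts were 4190 in WT, 2050 higher in the pellet and 2140 lower, and 4188 in IDRm, 2119 and 2069. RLE scaling moved the median of all genes from -0.02 to 0.14 in WT and from 0.05 to 0.17 in IDRm. The difference also rose with coding length over all genes (rank correlation 0.47 in WT and 0.54 in IDRm). Neither the genes and lists here nor those of the shifts below were corrected for length.

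Of 133 ribosomal protein genes, 130 were lower in the WT pellet and 1 higher (median -2.01, camera adjusted p = 1.56e-20, adjusted p = 0.298 with an estimated correlation). In IDRm 129 were lower and 1 higher, or 130 and 1 adjusted over the list alone (median -1.98, camera adjusted p = 1.48e-23, adjusted p = 0.282 with an estimated correlation). Proteasome genes were lower in 31 of 33 cases in WT (median -1.48, camera adjusted p = 3.65e-11, and adjusted p = 0.0484 with an estimated correlation). The same held for 30 of 33 in IDRm, or 30 with 1 higher adjusted over the list alone (median -1.33, camera adjusted p = 4.95e-11, and adjusted p = 0.0455 with an estimated correlation), with RPN13 at -2.61 ± 0.20 in WT. Mitochondrial ribosomal proteins had 56 of 66 lower and 2 higher in WT, or 56 and 3 adjusted over the list alone (camera adjusted p = 4.05e-10, and adjusted p = 0.0484 with an estimated correlation). Translation initiation factors had 19 of 26 lower and 1 higher in WT (camera adjusted p = 5.1e-05, and adjusted p = 0.0484 with an estimated correlation), with TIF11 at -2.62 ± 0.18. Histones had 8 of 10 lower in WT (camera adjusted p = 0.000436, adjusted p = 0.0534 with an estimated correlation). In IDRm 8 of 10 histones were lower as well (camera adjusted p = 0.000164, and adjusted p = 0.0455 with an estimated correlation). Respiratory chain genes had 29 of 34 lower and 2 higher in WT, or 30 and 2 adjusted over the list alone (camera adjusted p = 1.4e-06, adjusted p = 0.191 with an estimated correlation).

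Glucose-repressed genes were higher in the pellet in 17 of 20 cases in WT (median 1.12, camera adjusted p = 8.82e-06, and adjusted p = 0.0484 with an estimated correlation), with FBP1 at 2.42 ± 0.21 and GAL10 at 2.23 ± 0.18. The same held for 16 of 20 in IDRm (median 1.05, camera adjusted p = 2.28e-05, and adjusted p = 0.0455 with an estimated correlation). Plasma membrane transporters were higher in 36 of 37 cases in WT (median 1.09, camera adjusted p = 1.43e-09, adjusted p = 0.232 with an estimated correlation). The same held for 25 of 37 in IDRm (median 0.59, camera adjusted p = 6.12e-05, adjusted p = 0.479 with an estimated correlation), with PMA1, the plasma membrane proton pump, at 1.53 ± 0.17 in WT and 0.61 ± 0.17 in IDRm. The 28 Msn2/4 genes went both ways in WT, 12 higher and 9 lower, with a median of 0.29, a mean of -0.09 and camera upward (adjusted p = 0.369). DED1 (0.29 ± 0.14) and PAB1 (0.02 ± 0.16) were not called in WT, and DED1 was -0.41 there with total in place of soluble RNA.

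How heat moved transcripts between pellet and soluble RNA was read from the shift of that difference. Toward and away from the pellet are meant relative to the typical gene of the scaled libraries, and not as amounts in the cell. At 42 °C in WT, RPA190 (YOR341W, chromosome XV, 960987 to 965981), the largest subunit of RNA polymerase I, was among the genes that moved most toward the pellet, by 3.24 ± 0.22. Its soluble level went from 2667 CPM (SD 183) to 292 CPM (SD 53.1), while its pellet level was 3289 CPM (SD 197) and then 3383 CPM (SD 104). AVL9 (3.08 ± 0.29), the glutathione synthetase GSH2 (2.98 ± 0.17) and the splicing factor PRP39 (2.95 ± 0.26) followed, and LEC1 (2.93 ± 0.26). The order changed with total in place of soluble RNA, with RPA190 at 1.14, AVL9 0.74, GSH2 1.39 and PRP39 1.15, all called, and LEC1 0.15 and not called. Away from the pellet moved ARC40 (-2.36 ± 0.30), RPP1A (-2.10 ± 0.50), RPS2 (-2.02 ± 0.31) and TFS1 (-2.01 ± 0.23), which were -1.46, -0.58, -0.65 and -1.20 with total in place of soluble RNA. ARC40 was -1.70 and RPP1A -1.40, the latter not called, without the replicate 2 harvest of WT at 42 °C. SUI3 (YPL237W), a subunit of initiation factor 2, moved toward the pellet at 42 °C (1.28 ± 0.18). Of the 2353 called genes 1448 moved toward the pellet and 905 away, 61.5% toward, but 42.3% with RLE scaling, which moved the median of all genes from 0.06 to -0.18. With total in place of soluble RNA, 809 of the 2353 were called as well. DED1 moved away from the pellet (-0.95 ± 0.19), but was 0.35 with total in place of soluble RNA.

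Ribosomal protein genes moved away from the pellet at 42 °C in WT in 72 of 133 cases, with 1 toward it, or 81 and 1 adjusted over the list alone (median -1.08, camera adjusted p = 1.4e-16, adjusted p = 0.459 with an estimated correlation). Glycolysis genes moved away in 14 of 16 cases, 16 adjusted over the list alone (median -1.04, camera adjusted p = 2.85e-07, adjusted p = 0.459 with an estimated correlation), with PDC1 at -1.62 ± 0.23. Hsf1 genes moved away in 11 of 27 cases (median -0.46, or -1.08 without WT 30 °C soluble replicate 2, camera adjusted p = 7.82e-06, adjusted p = 0.459 with an estimated correlation), with AHA1 at -1.71 ± 0.19. Cell wall proteins moved away in 14 of 27 and toward in 1, or 15 and 1 adjusted over the list alone (camera adjusted p = 4.85e-06, adjusted p = 0.459 with an estimated correlation), with UTH1 at -1.68 ± 0.21. Ribosome biogenesis genes went both ways, 11 of 52 toward and 4 away, or 11 and 3 adjusted over the list alone, with a median of 0.15 (camera adjusted p = 0.776). That median was -0.09 with RLE scaling, -0.18 with the GC trend removed, -0.05 without WT 30 °C soluble replicate 2 and -0.02 without WT 42 °C soluble replicate 2. HSP104 (-0.46 ± 0.36), SSA4 (-0.41 ± 0.81) and PAB1 (0.17 ± 0.23) were not called. Without WT 30 °C soluble replicate 2 HSP104 (-1.08) and SSA4 (-1.95) were called.

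At 40 °C in WT, 34 of 133 ribosomal protein genes moved toward the pellet and 0 away, 35 adjusted over the list alone (median 0.68, camera adjusted p = 7.24e-07, adjusted p = 0.595 with an estimated correlation), with RPL4A at 1.83 ± 0.23, RPL15A at 1.78 ± 0.28 and RPL3 at 1.22 ± 0.23. Ribosome biogenesis genes moved toward the pellet in 21 of 52 cases, or 21 with 1 away adjusted over the list alone (median 0.45, camera adjusted p = 0.000134, adjusted p = 0.493 with an estimated correlation), with NOG2 at 2.20 ± 0.24 and RPA190 at 2.18 ± 0.21. The largest shifts were in ISA1 (2.83 ± 0.31), ALB1 (2.63 ± 0.25), EFM3 (2.52 ± 0.44), CSS1 (2.43 ± 0.24) and RCL1 (2.40 ± 0.22). On the other side they were in GCY1 (-2.22 ± 0.21), KRE29 (-2.16 ± 0.42), DCS2 (-2.13 ± 0.25), ALD3 (-2.08 ± 0.28) and SPI1 (-1.98 ± 0.37). Against total in place of soluble RNA ALB1 was 1.82, EFM3 1.36 and RCL1 1.75, all called, and CSS1 0.53 and not called. KRE29 was -1.70, DCS2 -1.46 and ALD3 -1.38 there. SPI1 was -2.70 without WT 30 °C soluble replicate 2. PAB1 moved 2.31-fold toward the pellet, and SUI3 by 1.81 ± 0.18 on the log2 scale. Hsf1 genes moved away in 11 of 27 cases, 12 adjusted over the list alone (median -0.56, camera adjusted p = 2.75e-06, adjusted p = 0.418 with an estimated correlation). Msn2/4 genes moved away in 10 of 28 with 1 toward, or 11 and 2 adjusted over the list alone (camera adjusted p = 6.5e-05, adjusted p = 0.418 with an estimated correlation). Of 1290 called genes 800 moved toward the pellet and 490 away, or 840 genes in all without WT 30 °C pellet replicate 1, and a model of those 4 groups alone called 2265. The share moving toward the pellet was 62.0%, but 40.4% with RLE scaling, which moved the median of all genes from 0.03 to -0.13.

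Between 40 and 42 °C in WT, 1512 genes shifted, 936 toward the pellet and 576 away, but 937 without WT 40 °C soluble replicate 1, 2353 without WT 42 °C soluble replicate 1, 822 in a model of those 4 groups alone and 452 with total in place of soluble RNA. TPM1, a tropomyosin, moved toward the pellet (2.54 ± 0.22), and RPS31 (-3.05 ± 0.59), RPP1A (-2.92 ± 0.51), RPP2B (-2.80 ± 0.47) and RPL16B (-2.80 ± 0.48) moved away. These were 1.97, -2.46, -1.85, -1.80 and -2.10 with total in place of soluble RNA. Without WT 42 °C soluble replicate 2 RPP1A was -2.28, RPP2B -2.04 and RPL16B -1.95, and RPS31 was not called without the replicate 2 harvest of WT at 42 °C (-2.5). Of 133 ribosomal protein genes 115 moved away and 1 toward, or 124 and 1 adjusted over the list alone (median -1.73, camera adjusted p = 4.86e-47, adjusted p = 0.551 with an estimated correlation). Over 5762 genes the rank correlation of this shift with coding GC content was -0.39, and that of the WT shift from 30 to 42 °C was -0.29. With the GC trend removed, 16 of the 55 called named genes of this shift lost the call or reversed.

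In IDRm at 42 °C against 30 °C, RPA190 was among the genes that moved most toward the pellet (3.38 ± 0.22), its soluble level at 2748 CPM (SD 257) and 197 CPM (SD 13.3). The nuclear import receptor PSE1 (3.18 ± 0.18), acetyl-CoA carboxylase ACC1 (3.02 ± 0.22), the coat protein SEC21 (3.01 ± 0.16) and glutamate synthase GLT1 (2.97 ± 0.20) followed, and PAB1 (YER165W, chromosome V, 510373 to 512106) moved by 1.77 ± 0.24. TFS1 (-2.84 ± 0.22), SPI1 (-2.66 ± 0.38) and RTS3 (-2.43 ± 0.37) moved away. This order also changed with total in place of soluble RNA, with RPA190 at 1.23, PSE1 1.55, ACC1 0.90, SEC21 1.58 and GLT1 0.98, and TFS1 at -2.21, SPI1 -2.06 and RTS3 -1.67, all called. Of 2282 called genes 1441 moved toward the pellet and 841 away, 63.1% toward, but 48.0% with RLE scaling, which moved the median of all genes from 0.03 to -0.14. Hsf1 genes moved away in 15 of 27 cases, 17 adjusted over the list alone (median -1.12, camera adjusted p = 3.82e-08, adjusted p = 0.514 with an estimated correlation), with MBF1 at -1.98 ± 0.24 and FES1 at -2.12 ± 0.43. Of 133 ribosomal protein genes 8 moved toward the pellet and 16 away, or 6 and 13 adjusted over the list alone (camera adjusted p = 0.0333, adjusted p = 0.805 with an estimated correlation). Their median was -0.20, but 0.09 without IDRm 42 °C pellet replicate 2 and 0.17 without IDRm 42 °C soluble replicate 1.

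At 40 °C in IDRm, 54 of 133 ribosomal protein genes moved toward the pellet, or 63 with 1 away adjusted over the list alone (median 0.87, camera adjusted p = 4.1e-15, adjusted p = 0.687 with an estimated correlation). ALB1 (2.81 ± 0.28), RPL11A (2.17 ± 0.34), ISA1 (2.13 ± 0.31) and PAB1 (1.55 ± 0.23) moved toward the pellet, and UIP4 (-2.84 ± 0.40), GCY1 (-2.49 ± 0.21) and SPI1 (-2.32 ± 0.38) away. ALB1 was 1.07 with total in place of soluble RNA, and UIP4 -3.44 without IDRm 30 °C soluble replicate 2. Msn2/4 genes moved away in 13 of 28 cases and toward in 1, or 16 and 1 adjusted over the list alone (median -0.95, camera adjusted p = 1.97e-07, adjusted p = 0.387 with an estimated correlation). Of 1342 called genes 796 moved toward the pellet and 546 away, 59.3% toward, but 36.7% with RLE scaling, which moved the median of all genes from -0.01 to -0.16. The count was 892 and 824 without IDRm 30 °C pellet replicate 1 and 2, 884 and 804 without IDRm 40 °C pellet replicate 1 and 2, 808 without IDRm 40 °C soluble replicate 2, and 2360.0 in a model of those 4 groups alone. Between 40 and 42 °C in IDRm 947 genes shifted, 690 toward the pellet and 257 away, with the fatty acid synthase FAS1 at 2.35 ± 0.22, or 0.80 with total in place of soluble RNA. Of 133 ribosomal protein genes 69 moved away, 93 adjusted over the list alone (median -1.01, camera adjusted p = 3.81e-36, adjusted p = 0.802 with an estimated correlation). That count of 947 was 579 without IDRm 40 °C pellet replicate 1, 587 without IDRm 42 °C pellet replicate 2, 570 without IDRm 40 °C soluble replicate 1, 560 without IDRm 42 °C soluble replicate 1, 369 in a model of those 4 groups alone and 477 with total in place of soluble RNA.

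**Figure D3:**
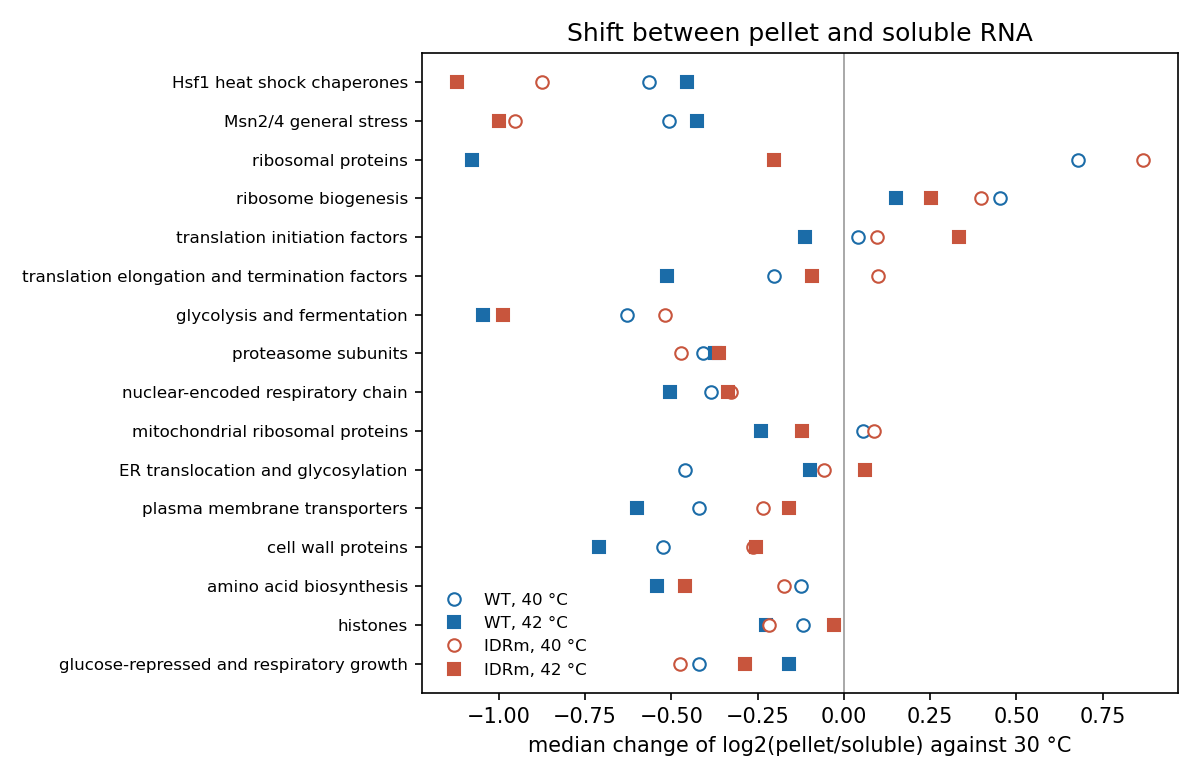
Median log2 shift of each gene list between pellet and soluble RNA against 30 °C (horizontal axis), for WT (blue) and IDRm (red) at 40 °C (open circles) and 42 °C (filled squares), 2 libraries per group and fraction. The ribosomal protein median was 0.68 in WT and 0.87 in IDRm at 40 °C and -1.08 and -0.20 at 42 °C. The last and some medians near 0 change sign with other libraries or with RLE scaling, which moves all medians down.

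Whether the strains differed in the split between pellet and soluble RNA was tested directly. At 30 °C the pellet-soluble difference was lower in IDRm for RPP0 (YLR340W), the ribosomal stalk protein, by -2.54 ± 0.28, ILV6 -2.31 ± 0.21, CAM1 (YPL048W), of the elongation factor 1 complex, -1.97 ± 0.20, KRE1 -1.82 ± 0.20 and MAE1, malic enzyme, -1.78 ± 0.27. These differences were in the soluble libraries, and whether preparation of those libraries differed between the strains is not known. RPP0 stood at 271 CPM (SD 8.16) in WT and 1610.1 CPM (SD 34.9) in IDRm soluble RNA, against 908 CPM (SD 75.2) and 929 CPM (SD 45.6) in the pellets. CAM1 stood at 90.0 CPM (SD 0.997) and 395 CPM in soluble RNA, 283 CPM (SD 26.1) and 316 CPM (SD 12.9) in the pellets, and 173 CPM (SD 62.9) and 142 CPM (SD 5.39) in total RNA. With total in place of soluble RNA, RPP0 was 0.58, ILV6 0.34, CAM1 0.44, KRE1 0.01 and MAE1 0.02, none of them called. Of 6141 genes 67 were called, 61 lower and 6 higher in IDRm, and 2 of the 67 were called with total in place of soluble RNA. The 61 genes were examined by fraction after their values were seen. Their median log2 difference between IDRm and WT in soluble RNA was 1.18 at 30 °C, 1.03 at 40 °C and 0.95 at 42 °C, with 60, 59 and 58 of 61 higher in IDRm. In total RNA the medians were -0.07, -0.00 and 0.08, and in the pellets -0.04, 0.09 and 0.04.

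That count of 67 was 30 and 35 without WT 30 °C pellet replicate 1 and 2, and 29 and 34 without IDRm 30 °C pellet replicate 1 and 2. It was 25 without WT 30 °C soluble replicate 1, and 38 and 37 without IDRm 30 °C soluble replicate 1 and 2. A harvest block gave 124, DESeq2 163, GC trend removal 119 and a model of those 4 groups alone 356. Plasma membrane transporters were called lower in 2 of 37 cases, 5 adjusted over the list alone (median -0.42, camera adjusted p = 8.43e-11, adjusted p = 0.595 with an estimated correlation). ER translocation and glycosylation genes had 0 of 29 called by edgeR, 2 lower adjusted over the list alone, with a median of -0.35 (camera adjusted p = 1.07e-06, adjusted p = 0.177 with an estimated correlation). Over all 6141 genes, 775 had an unadjusted p under 0.05. PMA1 (-0.92 ± 0.23), HSP104 (0.65 ± 0.36), DED1 (0.02 ± 0.19) and PAB1 (-0.06 ± 0.23) were not called, but PMA1 was called without WT 30 °C soluble replicate 2 (-1.12).

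At 42 °C the shift toward the pellet was larger in IDRm for 7 genes and smaller for 0. The largest were in SCW10 (YMR305C, chromosome XIII, 879063 to 880232), a cell wall glucanase, 2.22 ± 0.28, and the Golgi protein GVP36, 2.08 ± 0.29, both called without any 1 library. SCW10 stood at 139 CPM (SD 33.4) in WT and 45.9 CPM (SD 2.20) in IDRm soluble RNA at 42 °C, from 118 CPM (SD 6.74) and 128 CPM (SD 12.8) at 30 °C. With total in place of soluble RNA SCW10 was 0.81 and GVP36 0.99, neither called. Ribosomal protein genes had a median of 0.83 with 0 of 133 called by edgeR, also adjusted over the list alone (camera adjusted p = 2.26e-19, adjusted p = 0.578 with an estimated correlation). PAB1 (1.59 ± 0.33) and DED1 (0.77 ± 0.27) were not called. DED1 was called without WT 42 °C soluble replicate 1 (0.97), and PAB1 without IDRm 42 °C pellet replicate 1 (1.66) or WT 42 °C soluble replicate 1 (1.58) or 2 (1.60). The count of 7 was 4 without WT 30 °C pellet replicate 2, 3 without WT 42 °C pellet replicate 1, 4 without IDRm 30 °C pellet replicate 2. It was 19 and 22 without IDRm 42 °C pellet replicate 1 and 2, and 729 and 16 without WT 42 °C soluble replicate 1 and 2. RLE scaling gave 17, DESeq2 93, a harvest block 58, GC trend removal 31, pellet against total 28 and a model of the groups compared alone 0, and 663 genes had an unadjusted p under 0.05. At 40 °C edgeR called 0 genes and DESeq2 1, and 209 had an unadjusted p under 0.05. In the simulated comparison at 42 °C, 77.3% of 4-fold but 20.9% of 2-fold changes were found.

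How much of the mRNA was in the pellet was estimated for each harvest from the 3 libraries together. In WT the insoluble share was 20.2% (SD 3.20, n = 2) at 30 °C, 23.6% (SD 2.14, n = 2) at 40 °C and 32.9% (SD 5.06, n = 2) at 42 °C. In IDRm it was 5.68% (SD 2.77, n = 2), 13.3% (SD 0.616, n = 2) and 20.3% (SD 3.06, n = 2). WT exceeded IDRm by 14.6, 10.3 and 12.5 percentage points, or 3.56, 1.78 and 1.62 times, and all 6 WT harvests lay above both IDRm harvests of the same temperature. An exact two-sided permutation test over 216 splits of the harvests within temperature gave p = 0.00926, but harvests of a culture are not independent, and by culture the exact p was 0.333, the smallest that 2 against 2 cultures can give. From 30 to 42 °C the share rose by 6.79 and 18.5 points in the WT cultures and by 14.9 and 14.4 points in the IDRm cultures. With length trends removed, which was chosen after the data were seen, the shares at 30, 40 and 42 °C were 22.5, 19.4 and 30.6% in WT and 4.16, 9.13 and 15.3% in IDRm. The rise to 40 °C in WT turned into a fall there, and WT culture 1 fell from 29.2% at 30 °C to 25.6% at 42 °C.

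The median share per list, computed with the same fitted weights, followed the same order of strains. Over all genes it was 21.3, 28.3 and 43.2% in WT at 30, 40 and 42 °C and 6.20, 15.5 and 23.8% in IDRm. Transcripts of plasma membrane transporters had median shares of 37.4, 37.4 and 49.8% in WT and 8.74, 19.4 and 30.0% in IDRm. Those of glucose-repressed genes had 39.0, 41.3 and 54.3% in WT and 11.2, 22.9 and 31.6% in IDRm. Those of ribosomal proteins had 6.64, 14.9 and 7.95% in WT and 1.63, 8.97 and 6.72% in IDRm. From 30 to 42 °C in WT the median share went from 12.8 to 15.8% for glycolysis genes. It went from 15.1 to 22.3% for Hsf1 genes and from 27.1 to 33.5% for cell wall proteins. These lists moved away from the pellet only relative to the typical gene, and their estimated shares were not lower at 42 than at 30 °C. These list values carry no test of their own. All genes of a harvest share its 1 pair of weights, so the order of strains in the lists is no separate evidence of a strain difference. The estimate uses 1 weight per fraction for all genes, so a transcript that a library misrepresents is misplaced. CAM1 in IDRm, for instance, was lower in total RNA than in both fractions.

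**Figure D4:**
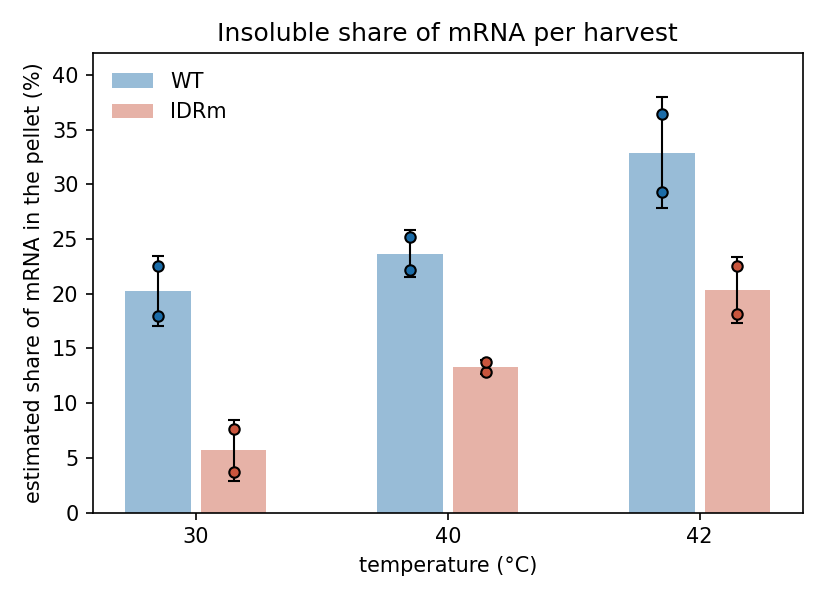
Estimated insoluble share of mRNA in percent (vertical axis from 0) by strain and temperature, with bars for the mean, points for the 2 harvests and error bars for the SD. WT was at 20.2, 23.6 and 32.9% and IDRm at 5.68, 13.3 and 20.3% at 30, 40 and 42 °C.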

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

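The results here came up because an interaction test found that the temperature effect differed between the strains. In total RNA the strains' changes differed in 100 genes at 40 °C and in 717 genes at 42 °C. The shift between pellet and soluble RNA at 42 °C differed in 7 genes. Of the tests below, those on a single library of the harvest, on mixing into the soluble library alone, on GC trends in the insoluble share and on the 61 genes were chosen only after the result was seen. The other tests were set before their own results, although removal of GC and length trends was itself chosen after the data were seen.

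Ribosome biogenesis transcripts fell further at 42 °C in IDRm than in WT, by a median of -0.88. The list was 0.46 higher in IDRm than in WT at 30 °C and 0.50 lower at 42 °C, so part of the difference lay at 30 °C. Trends with GC content did not account for it, since the median was -0.88 with those trends removed. The low level of AT-rich transcripts such as SLK19 and MAD1 in WT 30 °C total replicate 1 did not account for all of it either, since the median was -0.68 without that library. A biological difference between the strains therefore may underlie the part of -0.68, but with 2 cultures per strain a difference between cultures was not excluded.

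Of 27 Hsf1 genes, 16 in total, 18 in pellet and 23 in soluble RNA were higher in replicate 2 than in replicate 1 of WT at 30 °C, which matters because these libraries are the baseline of the heat comparisons. Whether heated RNA was mixed into all libraries of replicate 2 was not decided. In total RNA the Msn2/4 genes needed a share of -2.52% against 0.478% for the Hsf1 genes. In pellet RNA the Msn2/4 share was 0.343% against 2.764% for the Hsf1 genes, and in soluble RNA it was 0.934% against 3.403%. The negative share excludes such mixing only if both replicates started from equal Msn2/4 levels, which was not tested. Over all 28 Msn2/4 genes the median ratio in total RNA was 0.833, opposite in direction to the Hsf1 genes. The values argued against a change in 1 library alone. They do not exclude it, since the intervals below reflect spread over genes and not over libraries. In 3 of 3 libraries the excess over all 27 Hsf1 genes rose with their induction in IDRm, with rho at 0.694 (95% interval 0.368 to 0.864) in total, 0.933 (0.780 to 0.990) in pellet and 0.896 (0.719 to 0.967) in soluble RNA. An earlier test by the median ratio over all Hsf1 genes had found 1 library above 1.2 times (1.03, 1.07 and 1.26), and 3 over the strongly induced ones. It was replaced because weakly induced genes dilute that median. The total and pellet values, the lower being 0.694, argued against mixing into the soluble library alone as the source for the harvest. For the excess in the soluble library itself such mixing stayed open, since the Msn2/4 genes needed 0.934%, a ratio to the Hsf1 genes of 0.275 (95% interval 0.0998 to 0.736). A difference between the 2 harvests was not tested, because the design holds no group that separates them.

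The estimated insoluble share was higher in WT than in IDRm at each temperature, by 12.5 percentage points on average. Trends with GC content did not account for it (12.4 points with them removed), and neither did trends with coding length (14.6 points with them removed). The 61 genes whose soluble levels differed between the strains did not account for it either (11.7 points without them). A difference between the strains could explain the 12.4 points, but the exact p by culture was 0.333 and losses of pellet or soluble RNA during preparation were not measured. A wider difference in the preparation of the soluble libraries was not excluded, because it would go with the strain.

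The pellet-soluble difference of 61 genes was lower in IDRm than in WT at 30 °C, and their soluble levels differed at all temperatures by medians of 0.95 to 1.18, against -0.07 to 0.08 in total RNA. The soluble libraries representing these transcripts differently in the 2 strains could explain it. At 40 and 42 °C, in libraries that did not choose the genes, soluble and pellet levels added up to a median strain difference of 0.43 over the 58 nuclear protein-coding genes among them, but it was 0.02 in total RNA. The median excess was 0.45 (95% interval 0.25 to 0.60), and 56 of 58 genes had one. The median log2 ratio of that sum to the total level was -0.75, -0.48 and -0.11 in WT at 30, 40 and 42 °C. In IDRm it was -0.02, 0.05 and 0.19. The misfit was thus larger in WT at 30 °C, whose libraries chose the genes, and at 40 °C, but larger in IDRm at 42 °C. The sum rests on 1 pair of weights per harvest. Whether ribosomal RNA depletion or another step of preparation differed was not tested, since all soluble libraries of a strain would share it.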

How the results depend on the processing

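Most named genes kept their direction, and outside the comparisons between strains most also kept their call. Calls between the strains were often lost when 1 library was left out. The next values count a gene once per fit and include genes called in neither fit. Leaving out 1 library left 5426 values the same, 747 weaker, 31 stronger and 0 reversed. In these fits the lone library is assumed to vary like the other groups. Where no cause is given below, the cause was not tested.

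A model of only the groups compared has fewer libraries. It gave 80.0 genes for IDRm against WT at 30 °C, 43 and 408 for the strain difference at 40 and 42 °C, and 356, 16 and 0 for the pellet-soluble strain difference at 30, 40 and 42 °C. For the shifts it gave 2265 and 2360.0 for WT and IDRm at 40 °C, and 822 and 369 for WT and IDRm between 40 and 42 °C. DESeq2 gave 174 for the strain difference at 40 °C and 163, 1 and 93 for the pellet-soluble one at 30, 40 and 42 °C. At 42 °C that one was 17 with RLE scaling, 28 as pellet against total, 58 with a harvest block, 31 with the GC trend removed and 33 with a culture block as well. At 30 °C it was 124 with a harvest block, 119 with the GC trend removed and 112 with a culture block as well. Pellet against total gave 452 and 477 for the shifts between 40 and 42 °C in WT and IDRm. A culture or harvest block changed no other count by more than 1.5 times. Without the replicate 2 harvest of WT at 30 °C, chosen after seeing the data as were GC and length removal and exchanged pairs, the pellet-soluble counts were 748 (WT 40 °C shift), 43 (strains at 30 °C) and 3 (strains at 42 °C). Without that of WT at 42 °C the WT shift between 40 and 42 °C was 812. Exchanged pairs gave 3835 for WT at 42 °C in total RNA and 1799 for the WT shift at 40 °C. The insoluble share of IDRm at 40 °C was 14.1% by least absolute deviations. With length trends removed the share was 19.4% in WT at 40 °C, and 9.13 and 15.3% in IDRm at 40 and 42 °C. Of the list results, 15 of 169 held with an estimated correlation.

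Leaving out each library gave, for total RNA, 3789 to 4166 (WT 40 °C), 3153 to 3736 (WT 42 °C), 2109 to 2521 (WT 42 against 40 °C), 3816 to 3858 (IDRm 40 °C), 3313 to 3612 (IDRm 42 °C), 1617 to 1995 (IDRm 42 against 40 °C), 152 to 1483 (strains at 30 °C), 16 to 739 (strain difference at 40 °C) and 213 to 1509 (at 42 °C). For pellet against soluble it gave 3736 to 3806 (WT) and 3661 to 3739 (IDRm). For shifts it gave 840 to 1058 and 1828 to 2834 (WT 40 and 42 °C), 937 to 2353 (WT 42 against 40 °C), 804 to 971 and 1841 to 2474 (IDRm 40 and 42 °C), and 560 to 1420 (IDRm 42 against 40 °C). For the strains it gave 25 to 76 (30 °C), 0 to 0 (40 °C) and 3 to 729 (42 °C).

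Reversed values all came from GC removal or from total in place of soluble RNA. With the GC trend removed COX1 in WT at 42 °C was -0.0174 (-0.0226 with a culture block), and between 42 and 40 °C in IDRm VAR1 was 0.16 (0.13) and ATP6 0.0259 (0.0252). As pellet against total at 30 °C, DED1 was -0.41 and COX2 -0.0917 in WT, and PAB1 0.49 in IDRm. For the WT shift at 42 °C DED1 was 0.35, RPL3 0.80, RPN10 0.25, SDH4 0.23 and ALG5 -0.15, and between 40 and 42 °C DED1 was 0.31 and YOR1 -0.0658. For the strain difference at 30 °C RPP0 was 0.58, ILV6 0.34, CAM1 0.44, KRE1 0.00898, MAE1 0.0180, TEF4 0.53, PDC1 0.64 and SDH1 0.0906. Replicate differences exceeded counting noise in all 18 groups, with a chi-square per degree of freedom from 3.63 (IDRm 40 °C pellet) to 68.5 (WT 42 °C soluble RNA). Keeping ribosomal RNA was not run because the table holds no such genes.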

Other observations

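Genes called in both strains mostly moved in the same direction with heat. In total RNA at 40 °C, 3727 genes were called in both strains, 3717 of them in the same direction (r = 0.95 over 6090 genes), and at 42 °C 3043 and 2963 (r = 0.88). For the shift between pellet and soluble RNA, 840 genes were called in both strains at 40 °C and all 840 moved the same way, and at 42 °C 1580 and 1575 (r = 0.70 for each). Genes are not independent replicates, so these carry no test.

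Long transcripts lay more in the pellet. The rank correlation of the pellet-soluble difference at 30 °C with coding length was 0.47 in WT and 0.54 in IDRm over 5762 genes, and that of the shift at 42 °C was 0.40 and 0.44. Transcripts of mitochondrial genes made up 3.11% of pellet, 1.43% of total and 1.53% of soluble counts in WT at 30 °C, and 1.30, 1.27 and 0.454% at 42 °C.

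The neighbours of DED1 were not called between the strains at 30 °C, with BFR1 at -0.20, MRM1 at 0.28 and HIS3 at 0.32 on one side, and GEP3 at 0.09, NOC2 at 0.58 (adjusted p = 0.0814) and RET1 at 0.02 on the other. Medians over the 16 chromosomes lay between -0.08 and 0.02. Of the libraries, WT 42 °C soluble replicate 2 was the smallest, with 0.151% mitochondrial counts against 0.757% in replicate 1.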
